A study of Homo sapiens with 4 samples.

How the data were processed

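The experiment was a massively parallel splicing assay (MaPSy), in which a pool of minigenes is transfected into cells and the RNA made from each minigene is identified by sequencing. The pool carried 5307 variants at or near intron branch sites, taken from disease and population variant databases, each as a mutant oligonucleotide with its wildtype counterpart. Per the labels' protocols, HEK293T cells, a line derived from human embryonic kidney that is easy to transfect, were grown in 6-well plates and transfected with 1 µg of library DNA. RNA was taken 24 hours later, cDNA was made from 2 µg of total RNA with random hexamers, and the PCR amplicons were sequenced as single-end reads of 150 nt. The 4 samples are replicates 1 to 4 of a single group. Nothing in the labels says that they were separate transfections, so the spread between them may be technical. P-values of Fisher's exact test within a replicate measure counting error alone, and those of edgeR and limma the spread between these samples. All replicates share a single plasmid pool, so a fault in an oligonucleotide or its barcode would recur in all 4.

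The authors deposited, for each replicate, a table of read counts per oligonucleotide, as the file headers show: unspliced reads, spliced reads, canonical reads, non-canonical reads and, for mutants, reads spliced at an AG formed by the mutation. The values are whole numbers with no normalization. In all 40608 entries the spliced count equalled canonical plus non-canonical. HISAT2, SAMtools and the hg38 build are named in the submitters' processing notes, with no roles or settings, and how a read was assigned to an oligonucleotide or called canonical is not given in the sources used here. The counts are amplified reads, not molecules, since no molecular identifiers are described. Intervals and detection floors therefore cover counting error only.

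Each table held 10152 oligonucleotides, of which 5307 were mutants, 4830 were wildtype and 15 had no allele label. The 15 are described only among the closing observations. Mutants were joined to the wildtype of the same genomic window, and 845 mutants shared their wildtype with another mutant, so their comparisons are not independent. Each window spanned 113 nt, of which 78 were intronic and 35 were exonic. The named distance matched the genomic coordinate for all 4590 substitutions. Variant positions count upstream from the exon, with 1 as the last base of the intron, and bases are those of the transcribed strand: COL1A1 G9A has G in the wildtype and A in the mutant at distance 9. Genes were named by containment of the window in the RefSeq gene table for GRCh38.p14, protein-coding genes first. In this way 5091 pairs had 1 gene, from 3480 genes, 208 had several and 8 had none. The table used gives no strand, so a gene on the opposite strand cannot be excluded. Coordinates are in hg38, counted from 1.

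Non-canonical use is the percent of spliced reads that were non-canonical. The file names hint that the counted junctions may be limited to those with GT and AG ends, which the headers do not say, so junctions with other ends may be missing from these percentages. Splicing efficiency is the percent of spliced plus unspliced reads that were spliced. A pair was tested when both alleles had at least 20 spliced reads in every replicate, which 4792 of 5307 pairs did. Spliced reads are also part of efficiency, so a mutant that lost most of its splicing could miss this minimum and go untested. Counts of falls in efficiency may therefore be too low. Fisher's exact test, the test the study names, was run per pair and replicate, two-sided, on allele by product. P-values were adjusted by the Benjamini-Hochberg method over the tested pairs of each replicate. A pair was called when the adjusted p was under 0.05 in all 4 replicates with the same direction. The adjusted p printed for a pair is the largest of the 4. Effect sizes are log2 odds ratios with 0.5 added to each cell, as mean ± SD over the 4 replicates. Where 1 product was at 0 in all 4 replicates, the percent that 3 counts would give over the summed spliced reads is stated as the floor.

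The spread over replicates exceeded the counting error. The median ratio of the variance of a pair's log2 odds ratio over replicates to the variance expected from read counts was 2.55 for non-canonical use and 3.45 for efficiency. Binomial draws at the same counts gave 0.752 and 0.938. In the deepest 1197 pairs, with at least 948 spliced reads for both alleles, the ratios were 4.38 and 3.77. A Fisher test within a single replicate ignores this extra spread, which is why a call needed all 4 replicates. Data were simulated with the observed depth and a single extra variance for all pairs (4792 pairs, 200 of them changed). For non-canonical use the rule recovered 76% of pairs set at a log2 odds ratio of 3 and 42% at -3. For efficiency these shares were 42% and 92%. At 1 and -1 it recovered 10% and 6% for non-canonical use, and 2% and 12% for efficiency. It called 7 and 3 of 4592 unchanged pairs. Changes of up to 2-fold in the odds were therefore mostly missed. The simulated extra variance, 0.490 for non-canonical use and 0.365 for efficiency, was a difference of medians. It was not corrected for the low median of a variance over 4 values, so it lies below the observed spread. The shares recovered and the false calls may therefore look too favourable.

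The named pairs follow a rule set before the data were examined. For each comparison they are the called pairs, 1 per gene, with the largest absolute mean log2 odds ratio: 14 that rose and 8 that fell in non-canonical use, and 14 that fell and 8 that rose in efficiency. The 2 called pairs with the largest change in each of 10 gene lists were added. Genes named outside this rule, in short counts of the lists, were chosen after their values were seen. Some called pairs of the lists are not reported here. The lists covered hereditary cancer, cardiac disease, extracellular matrix and connective tissue, coagulation, lipid and intermediary metabolism, vision and hearing, neuromuscular and neurological disease, the immune system, the kidney, and genes known for disease branch site variants. Shares of called pairs were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment within each family of tests. Mean distances were compared by permutation tests with 100000 resamples. Shares carry 95% Wilson intervals.

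Alternatives were other count minimums (1, 50 and 100), summed counts, at least 3 of 4 replicates, the quasi-likelihood test of edgeR, limma on the log2 odds ratios as measured or centred on each replicate's median, minimum effects, other pseudocounts (1 and 0.1), and leaving out each replicate. Calls by position within the branch site and by source database were planned and are not analysed here, because neither property was tied to the pairs in the tables used. Substitutions were for the same reason compared with all other substitutions, not within a branch site position. Kinds of non-canonical product other than a new AG are not analysed here. The work used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and limma 3.58.1.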

Results

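RNA from 5307 mutant branch site minigenes and their wildtype counterparts was counted in 4 replicate libraries from transfected HEK293T cells. Replicates 1 to 4 held 15818746, 17097116, 15386421 and 15583005 reads. Most reads were spliced, at 96.9% ± 0.519 (mean ± SD, n = 4 replicates, as for all errors below unless stated). Non-canonical junctions made up 3.27% ± 0.0991 of the spliced reads. The median number of spliced reads per tested mutant lay between 700 and 759 over the replicates, but that of unspliced reads only between 25 and 33, so efficiency rests on few unspliced reads. Reads per oligonucleotide correlated between replicates with Pearson's r of 0.966 to 0.983 on a log scale.

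The first question was whether a branch site variant changes the use of non-canonical splice sites. Non-canonical use rose in 194 of 4792 tested pairs and fell in 76, which together were 5.63% of the pairs. Among the 194 the median share of non-canonical reads was 2.95% for the wildtype and 19.6% for the mutant. Among the 76 that fell it was 7.69% for the wildtype and 2.41% for the mutant. Over all tested pairs the medians hardly differed, at 1.57% and 1.62%. The mutant used non-canonical sites in over 50% of spliced reads in 47 called pairs and in over 90% in 16.

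In 4 pairs no canonical read was left in the mutant in any replicate. A deletion of 11 nt that starts 12 nt from an exon of ANO5, an anoctamin membrane protein linked to muscular dystrophy, took non-canonical use from 1.65% ± 0.596 to 100% ± 0, with a floor of 0.216% for canonical reads. It lies at chromosome 11, 22262117 to 22262127 (hg38), and covers intron distances 12 to 2, so it takes the A of the acceptor AG itself. SNHG1 G9A, in a noncoding host gene of small nucleolar RNAs, went from 1.47% ± 0.795 to 100% ± 0, on as few as 35 mutant reads in a replicate and with a floor of 1.52%. KEL G21T, in the Kell blood group gene, went from an already leaky 33.6% ± 3.99 to 100% ± 0, with a floor of 0.0597%. CHD4 A16T, in a chromatin remodeller, went from 26.7% ± 2.29 to 100% ± 0, with a floor of 0.182%.

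In 9 of the other 10 largest rises most non-canonical reads used an AG that the variant itself formed. MSH6 T7G, in a mismatch repair gene (chromosome 2, 47804903, intronic, 7 nt from the exon), rose from 0.576% ± 0.475 to 92.4% ± 0.800, and 99.4% of the mutant's non-canonical reads were at the new AG. COL1A1 G9A, in a type I collagen gene, rose from 1.94% ± 2.24 to 96.3% ± 0.618. ERCC6 A26G, in a gene of transcription-coupled DNA repair, rose from 4.05% ± 6.32 to 95% ± 2.02. PEX6 C15G, in a peroxisome biogenesis gene, rose from 1.57% ± 1.26 to 94.4% ± 0.248. POMT2 G14A, in a gene of protein O-mannosylation, rose from 3.13% ± 0.721 to 95.9% ± 0.677, and GLB1 C10G, in the gene of lysosomal beta-galactosidase, from 4.64% ± 1.95 to 96.3% ± 0.400. NBN A13G, in a DNA double-strand break repair gene, and ALDH7A1 T24G, in a gene of lysine breakdown, started from near 0, at 0.0371% ± 0.0742 and 0.0304% ± 0.0176, and reached 52.0% ± 2.73 and 28.2% ± 2.96. UBR1 T6G, in a ubiquitin ligase gene, reached 61.4% ± 14.8 on as few as 35 mutant reads. The exception was COL7A1 A19G, in the collagen gene of the skin's anchoring fibrils (chromosome 3, 48575921), which rose from 0.274% ± 0.392 to 87.2% ± 6.00 with no read at a new AG. Over these 10 pairs the log2 odds ratio ran from 8.79 ± 1.82 in UBR1 to 11.48 ± 1.47 in MSH6, and the largest adjusted p was 6.74e-19 (Fisher's exact test, n = 4).

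**Figure D1:**
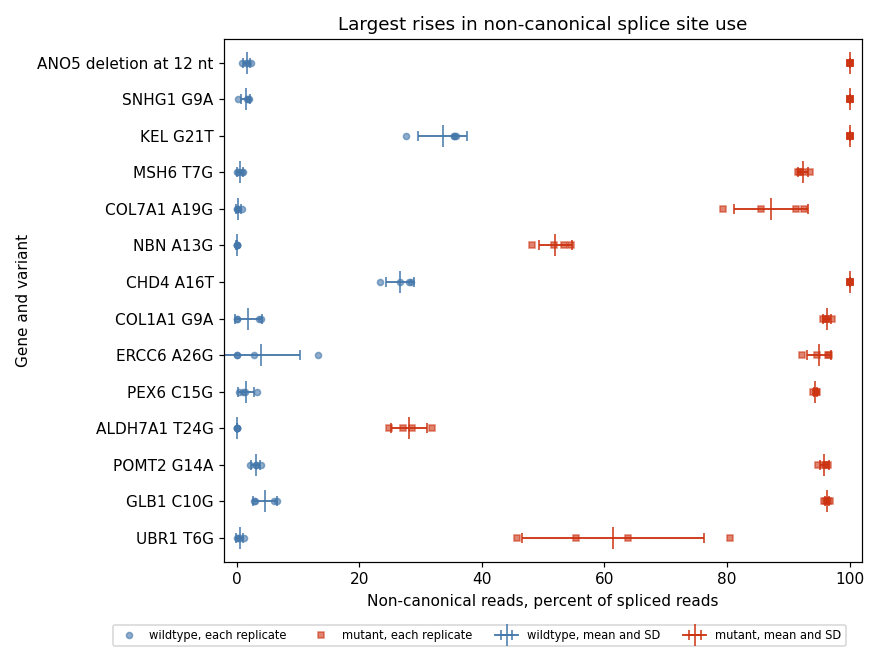
Percent of spliced reads that were non-canonical (x axis) for the 14 pairs with the largest rise (y axis, gene and variant, largest at the top), with wildtype in blue circles, mutant in red squares, each replicate as a point, and mean ± SD as bars (n = 4). KEL and CHD4 start above 25% in the wildtype, and the mutants of ANO5, SNHG1, KEL and CHD4 sit at 100%.

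The largest falls were in pairs with a leaky wildtype. EPS8 T30A, in a gene of actin regulation, fell from 6.77% ± 0.644 to 0.0415% ± 0.0492 (log2 odds ratio -7.82 ± 1.89). BAX G26A, in a gene that promotes apoptosis, fell from 7.78% ± 1.81 to 0 non-canonical reads in all 4 replicates, with a floor of 0.0978%. EIF3F A27G, in a translation initiation factor gene, and FCN3 A23C, in a lectin gene of the complement system, also fell to 0 in all 4, from 5.46% ± 1.63 and 6.18% ± 2.81, with floors of 0.278% and 0.432%. FTH1 C56T, in a ferritin subunit gene, fell from 13.9% ± 3.04 to 0.446% ± 0.634, and DLG5 G26C, in a scaffold protein gene, from 20.1% ± 3.62 to 1.01% ± 0.843. BACE1 G18A, in a beta-secretase gene, fell from 8.82% ± 3.94 to 0.325% ± 0.462, and G22T in a window shared by PFKFB2 and YOD1 from 18.1% ± 11.6 to 0.625% ± 0.922. Neither of these passed in limma. Adjusted p-values of these 8 reached up to 0.0258, in FCN3 (Fisher's exact test, n = 4). Of the 76 falls, 61 lay among the 1198 pairs with a wildtype share of 3.43% or more. A tighter wildtype leaves few non-canonical reads to lose, so a fall could hardly be called there.

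The log2 odds ratios of 2 replicates correlated across the 4792 pairs with r of 0.351 to 0.429 (Spearman's correlation 0.258 to 0.311; pairs are not independent replicates), and differences in percent, which weigh large changes more, with r of 0.788 to 0.849. Of all tested pairs, 30.3% had a single sign in all 4, against 12.5% if signs were independent and equally likely. With few non-canonical reads, the sign can follow the constant added to each cell and the read depths of the alleles. ARHGEF25 G27A, for example, went from 0% to 0.407% non-canonical but had a log2 odds ratio of -2.37. Read depths repeat between replicates, so 12.5% is not the level without a change, and the excess cannot be read as agreement of effects. Within a single replicate 1125 to 1605 pairs passed the threshold, so most of those were not repeated in all 4. The limma test called 143 rises and 57 falls, and 120 of the 270 calls were shared with it.

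The second question was whether variants change splicing efficiency. Efficiency fell in 157 of 4792 pairs and rose in 61, together 4.55%. Among the 157 the median share of spliced reads was 96.1% for the wildtype and 87.2% for the mutant, and among the 61 it was 87.1% and 95.8%. Efficiency fell by at least 10 percentage points in 71 pairs and rose by as much in 24. In 11 called pairs less than 50% of the mutant's reads were spliced.

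The largest fall in log2 odds ratio was in ECPAS A55G, in a gene of a proteasome-associated protein (chromosome 9, 111440576, intronic, 55 nt from the exon), from 97.4% ± 0.417 to 41.5% ± 10.0 spliced (log2 odds ratio -5.74 ± 0.73, adjusted p = 5.44e-41, Fisher's exact test, n = 4). COL4A5 A40G, in a basement membrane collagen gene (chromosome X, 108606702), fell further in percentage points, from 91.4% ± 3.12 to 26.7% ± 2.19. Other A-to-G changes fell to below 50% spliced as well: UBR4 A22G, in a ubiquitin ligase gene, from 94.4% ± 0.761 to 47.2% ± 6.97, and NDST1 A21G, in a gene of heparan sulfate synthesis, from 89.2% ± 2.81 to 40.5% ± 14.3. CELSR2 A25G, in an adhesion receptor gene, fell from 94.2% ± 2.12 to 60.9% ± 3.97, and TMEM268 A24T from 95.4% ± 2.26 to 66.1% ± 15.7. T6G changes lowered efficiency in UBR1, from 95.8% ± 1.87 to 40.7% ± 14.2, and in FAH, a gene of tyrosine breakdown, from 93.2% ± 5.50 to 59.2% ± 10.4.

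Short insertions and deletions made up 5 of the 14 largest falls. A deletion of 8 nt at 21 nt from an exon of HNRNPAB, a gene of an RNA-binding protein, went with a fall from 97.7% ± 1.44 to 54.9% ± 5.29. An insertion of 1 nt at 15 nt from an exon of SERPINA1, the gene of alpha-1 antitrypsin, went with a fall from 97.0% ± 0.405 to 60.2% ± 3.47. Deletions of 4 nt in PPP1CA, a phosphatase gene, and of 13 nt in LAMA1, a laminin gene, left 91.7% ± 2.40 and 83.9% ± 2.72 spliced, against 98.8% ± 1.60 and 98.3% ± 0.899 in the wildtype. The ANO5 deletion and SNHG1 G9A, which had lost all canonical reads, also fell, to 87.8% ± 4.34 and 79.0% ± 4.76. Except in LAMA1, the mutants of these 14 had fewer spliced reads than their wildtypes. ECPAS had 42 to 68 per replicate against 2076 to 2354. A loss of splicing itself lowers this number, and whether read depth shaped the falls was not tested. As a class, deletions (10 of 441 lower) and insertions (3 of 222 lower) did not differ from other pairs, with adjusted p = 0.382 and 0.230 (Fisher's exact test, 44 tests).

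**Figure D2:**
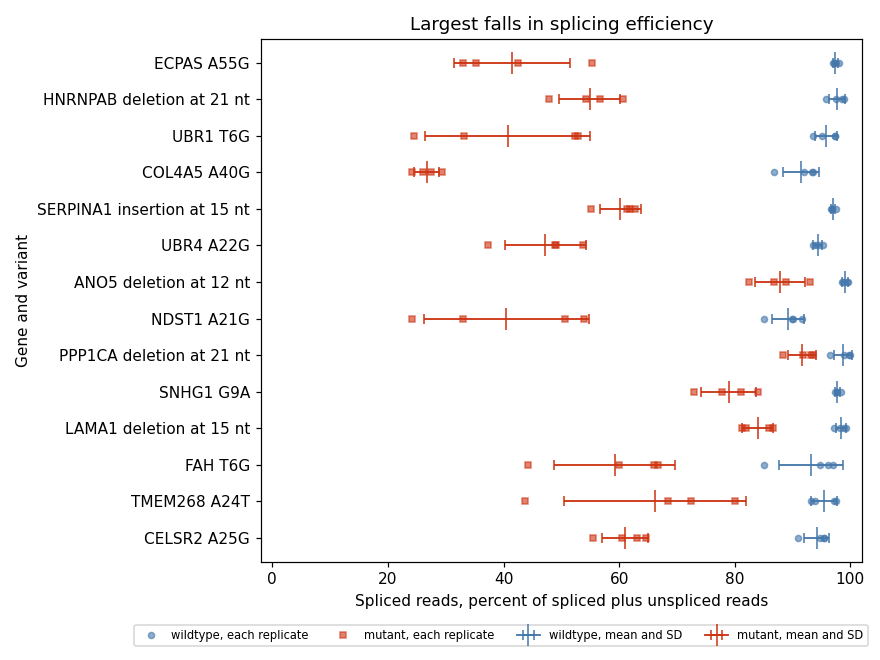
Spliced reads as a percent of spliced plus unspliced reads (x axis) for the 14 pairs with the largest fall in efficiency (y axis, gene and variant, largest at the top), with wildtype in blue circles, mutant in red squares, each replicate as a point, and mean ± SD as bars (n = 4). COL4A5 A40G has the lowest mutant mean, at 26.7%, and the replicates of UBR1, NDST1 and TMEM268 lie far apart.

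The largest rises started from a wildtype with unspliced reads to lose. A deletion of 7 nt at 77 nt from an exon of ACADVL, a gene of fatty acid oxidation, went with a rise from 55.6% ± 15 to 96.0% ± 1.48, on as few as 20 wildtype reads in a replicate. BAP1 G21A, in a deubiquitinase and tumour suppressor gene (chromosome 3, 52402961), rose from 61.7% ± 6.78 to 92.9% ± 1.64, and LEPROTL1 T27G from 78.9% ± 4.76 to 97.9% ± 0.630. ULK3 C28T, in a kinase gene, rose from 58.5% ± 27.0 to 93.6% ± 2.64, and ARHGEF25 G27A from 73.8% ± 7.44 to 94.2% ± 2.95. PPP1R16B A25G, FAAP20 C26A and an insertion of 1 nt in CERS2 rose to 98.7% ± 0.215, 99.4% ± 0.128 and 97.6% ± 1.51, from 89.5% ± 5.10, 95.9% ± 1.30 and 87.1% ± 2.64. Except in CERS2, the wildtypes of these 8 had fewer spliced reads than their mutants. FAAP20 had 355 to 519 per replicate against 19891 to 26523. Whether read depth shaped the rises was not tested. Of the 61 rises, 49 lay among the 1198 pairs with a wildtype efficiency of up to 94.6%. Above that, the ceiling of 100% leaves little room for a rise. Adjusted p-values of these 8 pairs reached up to 0.0444, in ULK3 (Fisher's exact test, n = 4).

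Log2 odds ratios of efficiency in 2 replicates correlated across pairs with r of 0.190 to 0.333 and differences in percent with r of 0.429 to 0.555. Of all tested pairs, 26.8% had a single sign in all 4. The limma test on the 4 log2 odds ratios, which uses their spread, called only 47 falls and 14 rises, and 57 of the 218 calls were shared with it.

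The 2 readouts moved together in part of the pairs. Efficiency fell in 46 of the 194 pairs with a rise in non-canonical use, 23.7%, against 2.41% of the other pairs (6.36 expected if independent, p = 1.2e-28, Fisher's exact test). UBR1 T6G, SNHG1 G9A and the ANO5 deletion were among the largest changes in both. Only 3 pairs fell and 4 rose in efficiency with a change of non-canonical use in the same direction, and 3 moved the opposite way, with a fall in non-canonical use and a rise in efficiency. In all, 432 pairs, 9.02%, were called in at least 1 comparison. Both readouts of a pair come from the same reads and share the spliced counts.

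A new AG formed by the variant accounted for a minority of the rises. Reads at a new AG were seen in all 4 replicates in 80 tested pairs. Non-canonical use rose in 39 of these, 48.8%. New-AG reads are themselves non-canonical reads of the mutant, so this share was not tested against other pairs. Efficiency fell in 25% of the 80 and in 2.91% of the others (p = 4.0e-13, Fisher's exact test). Reads at a new AG in every replicate are more likely in deep mutants, where falls are easier to call. Of the 80 pairs, 39 were A-to-G changes, the class with most falls. The test was matched for neither depth nor substitution, so it does not tie the falls to the new AG. In 29 of the 194 rises, 14.9%, at least 50% of the mutant's non-canonical reads were at the new AG, while 148 of the 194 had no such read in any replicate. Pairs with no such read include COL7A1 A19G and TSC2 A19G, so their non-canonical reads used other sites.

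The kind of substitution was compared next, each against all other substitutions. Removal of an A lowered efficiency in 86 of 1352 pairs, 6.36%, against 2.09% of other substitutions (adjusted p = 4.8e-10, Fisher's exact test, 44 tests). A-to-G changes led, with 65 falls in 826 pairs, 7.87%, against 2.39% (adjusted p = 1.6e-10, 48 tests). They also raised non-canonical use in 56 pairs, 6.78%, against 3.48% (adjusted p = 0.00133). Falls in efficiency did not separate for the other losses of an A. They were 5.02% against 3.40% for A to C (adjusted p = 0.390, Fisher's exact test) and 3.26% against 3.51% for A to T. Gain of a G lowered efficiency in 84 of 1255 pairs, 6.69% (adjusted p = 8.2e-11), a class that overlaps with A-to-G changes. G-to-A changes went the other way: efficiency rose in 15 of 460 pairs, 3.26%, against 1.04% (adjusted p = 0.00493), and fell in 6. Falls were rare for G-to-T changes, 1 of 321, and C-to-T changes, 8 of 625 (adjusted p = 0.00296 and 0.00493). Loss of a T gave falls in 31 of 764 pairs and rises in only 2, of which the low share of rises passed the test (adjusted p = 0.0131) and the falls did not (adjusted p = 0.436).

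**Figure D3:**
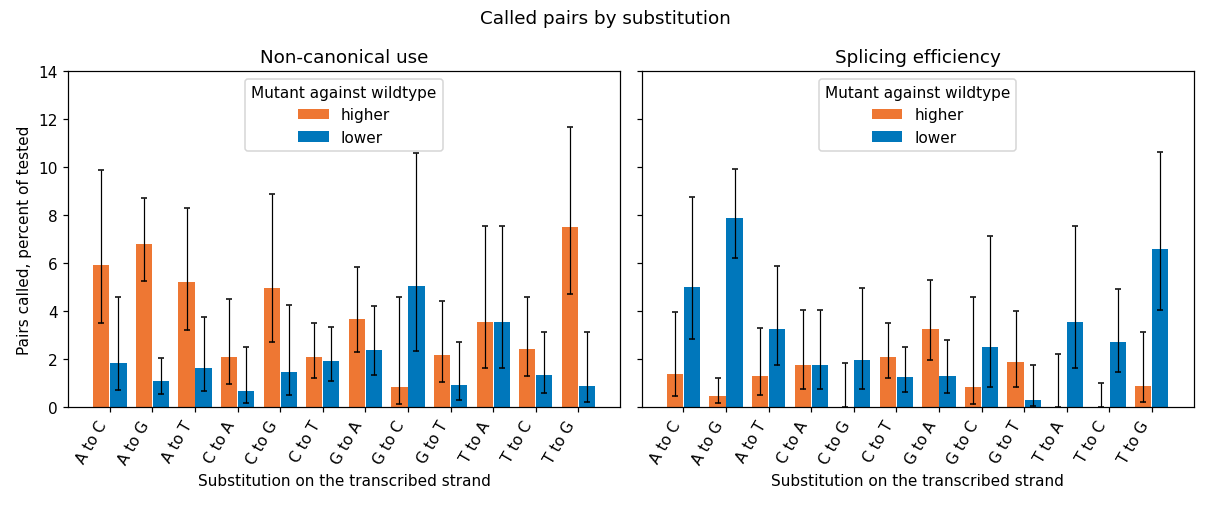
Percent of tested pairs called (y axis) for each substitution on the transcribed strand (x axis), for non-canonical use on the left and splicing efficiency on the right, with rises in orange, falls in blue and 95% Wilson intervals as error bars. A to G has the tallest bar for falls in efficiency, at 7.87%, and G to A the tallest for rises, at 3.26%.

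Variants called for a rise in non-canonical use or a fall in efficiency lay closer to the exon than the rest. The mean distance was 26.2 nt in pairs with a rise in non-canonical use against 30.6 nt in all others (permutation p = 1e-05, the smallest that 100000 resamples can give), and 27.3 against 30.5 nt for a fall in efficiency (permutation p = 0.00028). With pairs in 4 groups by distance, from the nearest to the farthest, the share of rises in non-canonical use was 6.42%, 4.43%, 2.79% and 2.03%, and that of falls in efficiency 5.19%, 3.23%, 2.07% and 2.19%. Falls in non-canonical use and rises in efficiency did not differ in mean distance (permutation p = 0.484 and 0.546). Within 15 nt of the exon, a limit chosen after the data were seen, non-canonical use rose in 17 of 125 pairs, 13.6%, against 3.79% beyond (p = 9e-06, Fisher's exact test). In 9 of these 17 rises at least 50% of the mutant's non-canonical reads were at an AG formed by the variant. Another was the ANO5 deletion, which takes the A of the acceptor. Efficiency fell within 15 nt in 10.4% against 3.09% (p = 0.000194, Fisher's exact test). Efficiency also rose there in 6 of 125 pairs, 4.80% against 1.18% (p = 0.0048, Fisher's exact test).

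**Figure D4:**
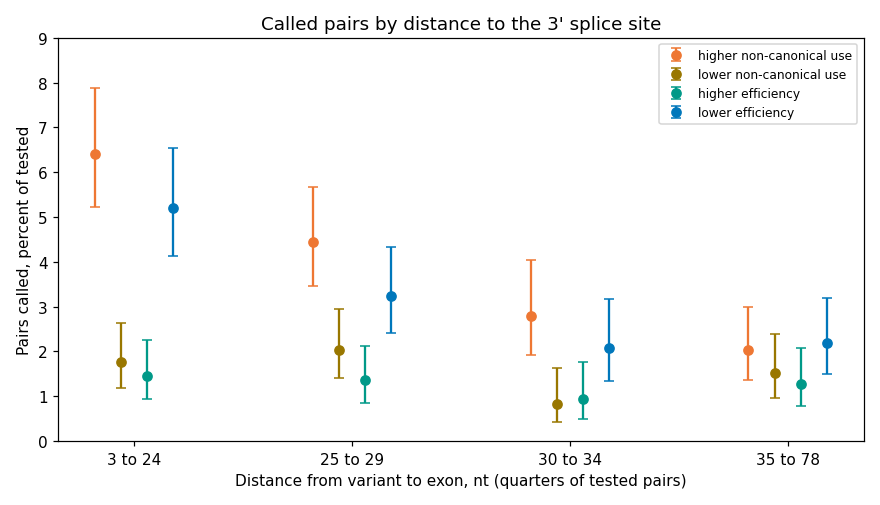
Percent of tested pairs called (y axis) in 4 groups of the distance between variant and exon in nt (x axis), with points for each direction of each readout and 95% Wilson intervals as error bars. Rises in non-canonical use drop from 6.42% at 3 to 24 nt to 2.03% at 35 to 78 nt.

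Among the gene lists, extracellular matrix genes had 70 tested pairs in 21 genes. Efficiency fell in 6 of them (COL1A2, COL4A5 in 2 pairs, COL5A1, COL7A1 and FBN2) and rose in COL6A3, 10.0% against 4.52% of other pairs (adjusted p = 0.204, Fisher's exact test, 20 tests over the lists). COL5A1 A23T, in a fibrillar collagen gene, fell from 96.6% ± 0.854 to 81.4% ± 9.20 spliced. Non-canonical use rose in COL1A1, COL3A1, COL4A5 and COL7A1 and fell in FBN1, 7.14% of pairs (adjusted p = 0.988). Adjusted over the list alone, the counts were again 7 and 5. The kidney list had only 4 tested pairs, of which 3 fell in efficiency, COL4A5 in 2 and PKHD1 (75% against 4.55%, adjusted p = 0.00745, Fisher's exact test, and 4 when adjusted over the list alone). COL4A5 is in the extracellular matrix list too, and with 1 pair per gene the kidney list no longer passed (adjusted p = 0.121). COL4A5 A18G combined a fall in efficiency, from 98.4% ± 1.44 to 92.9% ± 4.20, with a rise in non-canonical use from 0.911% ± 1.06 to 19.1% ± 4.70, of which 96.5% was at a new AG.

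Hereditary cancer genes had 69 tested pairs, of which 7 fell in efficiency (among them BRCA1, MSH6, RB1 in 2 pairs, TSC2 and XPC) and none rose, 10.1% against 4.52% (adjusted p = 0.204, Fisher's exact test). TSC2, a tumour suppressor gene that restrains growth signalling, had 3 named pairs in separate windows. TSC2 A19G (chromosome 16, 2072222) rose in non-canonical use from 20.1% ± 3.31 to 94.0% ± 1.14, TSC2 G26A fell from 11.7% ± 5.25 to 3.60% ± 0.818, and TSC2 T23G fell in efficiency from 91.2% ± 3.71 to 61.0% ± 4.63. RB1 T28C fell from 98.1% ± 0.812 to 94.1% ± 1.48 spliced. Non-canonical use rose in BRCA2, MSH6, NF1 and TSC2 and fell in BMPR1A and TSC2 (adjusted p = 0.699). The counts adjusted over the list alone were 7 and 6. In the list of genes known for disease branch site variants, efficiency fell in 4 of 33 pairs (COL5A1, FBN2, TSC2 and XPC, adjusted p = 0.252), and the 2 changes in non-canonical use were those of TSC2 (adjusted p = 1). Adjusted over the list alone they were 4 and 2.

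In the immune list, 2 of 7 pairs fell in efficiency, both at a single base of BTK, the tyrosine kinase of B cell development (adjusted p = 0.204, Fisher's exact test). BTK A23G (chromosome X, 101354717) went from 94.6% ± 2.55 to 70.1% ± 2.76 and BTK A23C from the same wildtype to 80.4% ± 3.10. Of 25 cardiac pairs, efficiency fell in MYH7 A23T, a cardiac myosin gene, from 92.3% ± 0.830 to 83.6% ± 4.67, and rose in LMNA C7T, in the lamin A gene, from 78.2% ± 9.73 to 93.5% ± 6.65 (adjusted p = 0.714 for the list, with 3 calls adjusted over the list alone). Non-canonical use rose in LAMP2 A38G, in a lysosomal membrane gene, from 3.83% ± 0.690 to 6.77% ± 0.898, but did not pass in limma (adjusted p = 0.217, against 0.0451 in edgeR). Of 36 metabolic pairs, non-canonical use rose in 3, among them ACADM and CPS1, and efficiency rose in ABCA1 and ACADVL. ACADM G18A, in a gene of medium-chain fatty acid oxidation, rose from 26.8% ± 4.50 to 67.2% ± 1.45. SPG11 C3T was the only call of 10 neuromuscular and neurological pairs, with 92.8% ± 1.16 against 82.1% ± 4.06 spliced. No pair was called among 4 in coagulation and 5 in vision and hearing genes, too few to exclude shares like those of other genes. EdgeR called none of the 4 but 20% of the 5, and 10% of the neuromuscular and neurological pairs, for non-canonical use. The efficiency changes of LMNA, MYH7 and SPG11 did not pass in edgeR, with adjusted p of 0.0673 to 0.0882.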

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

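Tests chosen only after the result was seen were those of the allele swaps, of A losses by distance, of falls and other mutants in held-out replicates, and of new AG sites by distance and depth.

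A replicate far from the other 3 was looked for in 66 sets of 4 values, and 3 were found where chance gives about 1 in 20, or 3.3. In BAX G26A the log2 odds ratio of non-canonical use was -7.41 in replicate 2 and -6.87 to -6.77 in the others. No non-canonical read of the mutant was counted in any of the 4. In the ACADVL deletion that of efficiency was 3.80 in replicate 3 and 4.46 to 4.58 in the others, and in LEPROTL1 T27G it was 3.0 in replicate 1 and 3.82 to 3.97 in the others. The 3 lay in different replicates, and each call held without any single replicate.

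The 15 oligonucleotides with no allele label, in windows of HBB, a beta-globin gene, and VASP, an actin regulator gene, gave signal that no comparison above uses. A VASP construct is named wtm and all others bp with a number. No key to these names is given, so which is a control is not known. Each replicate had more than 3 non-canonical reads in HBB bp1, 0.469% ± 0.224 of spliced reads, and in VASP bp13, 1.88% ± 0.313, bp0, 4.82% ± 1.77, bp1, 7.65% ± 0.756, bp12, 51.9% ± 6.77, and bp2, 53.1% ± 7.23 (n = 4). The remaining VASP constructs had 0 such reads in some replicate: wtm, 1.17% ± 1.23, bp3, 0.486% ± 0.330, and bp23, 5.06% ± 6.40 on 15 to 30 spliced reads.

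Swapping the 2 allele names in some replicates makes 8 splits, too few for a share under 0.05. Only 1 of the 8, the real one, gave as many calls in each comparison: 270 for non-canonical use, with 6 as the highest other, and 218 for efficiency, also with 6.

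Substitutions that removed an A and those that created one moved efficiency apart, with mean log2 odds ratios of -0.28 (n = 1352) and 0.03 (n = 914), a difference of -0.32. The difference was -0.28 within levels of wildtype efficiency, which argues against regression to the mean, -0.37 in the deeper part of unspliced counts, and -0.30 without pairs with any new-AG read (each permutation p = 1e-05, the smallest possible). The median log2 odds ratio of efficiency was -0.28 for A to G, -0.09 for A to C and -0.02 for A to T. It was -0.30 for T to G and -0.16 for C to G, so the contrast does not separate loss of an A from gain of a G. Loss of a branchpoint adenosine may contribute: A losses 18 to 40 nt from the exon had a lower median than other A losses, by -0.16 (95% bootstrap interval -0.26 to -0.03, permutation p = 0.013). T losses in this band had as low a median, -0.21, but did not differ from T losses elsewhere (permutation p = 0.452), and G losses were higher in the band, by 0.15 (permutation p = 0.0243). The share of called falls of A in the same band, 6.65% against 4.64%, did not separate (p = 0.342, Fisher's exact test), and whether the lost A was the branchpoint was not tested.

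Non-canonical use fell mostly where the wildtype was leaky, which the room for a fall alone would give. Rises were most frequent there too, in 7.68% of pairs, which room for a fall does not address. Whether high wildtype values were selected by sampling was tested by choosing pairs in replicates 1 and 2 and measuring them in replicates 3 and 4. The 129 pairs with a leaky wildtype called lower in the first 2 kept a median log2 odds ratio of -0.90 (95% bootstrap interval -1.17 to -0.72) in the others. Over all tested pairs it was 0.10. This argues against sampling within single replicates as the whole source of these falls. Sampling at a step that the replicates share would recur in all 4 and was not tested. How far the values shrank from replicates 1 and 2 is not given. A faulty wildtype stays open. It was examined in all wildtypes with a mutant called lower in replicates 1 and 2, leaky or not. Their 30 other mutants had a median of -0.16 in replicates 3 and 4, with an interval of -0.79 to 0.23. That interval holds both the 0.10 of all pairs and the -0.75 of the called mutants. Over all 4 replicates, 0 of 13 other mutants were called lower and the median of their differences from the called mutant of the same wildtype was 0.84 (interval 0.18 to 1.08), but the called mutants were chosen for low values in these replicates. For the 68 called pairs with no other tested mutant it cannot be told apart from an effect of the variant, since no other mutant shares that wildtype. In the 2 of CDC27, 1 base change fell alike against 2 separate wildtypes (log2 odds ratio -1.60 and -1.47). Their windows have different exon starts, so the canonical site differs and the 2 falls need not be the same event.

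New AG sites close to the exon took more of the spliced reads than those farther away. Among the 80 pairs with new-AG reads in all 4 replicates, over 50% of the mutant's spliced reads were at the new AG in 9 of 10 within 15 nt, all but FAH T6G with 43.9%, against 5 of 70 beyond (p = 8.1e-08, Fisher's exact test). The contrast held among mutants with at least 500 spliced reads in every replicate, 6 of 6 against 4 of 60 (p = 2.3e-06, Fisher's exact test). Shallow mutants alone therefore do not account for it. Depth was not matched: among the 80 pairs the fewest spliced reads of a mutant had a median of 783.5 within 15 nt and 1407 beyond. Deeper mutants can enter the 80 with smaller shares of new-AG reads, so a part played by depth stays open. With the limit at 10 or 20 nt the share within was 83.3% or 50%, and that beyond 12.2% or 6.67%. No biological explanation was tested by a group of the design for these patterns.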

How the results depend on the processing

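Tests chosen only after the result was seen were those on substitutions alone, with at least 10 unspliced reads, of lists without genes in another list, with other limits for new AG sites, and with edgeR calls for new AG sites and for pairs called in both comparisons. No result reversed. Calls of non-canonical use (270: 194 higher, 76 lower) moved to 2073 (1158, 915) with counts summed over replicates, 455 (292, 163) with 3 of 4 replicates and 133 (114, 19) with a difference of at least 10 points. Efficiency calls (218: 61 higher, 157 lower) moved to 2124 (905, 1219), 415 (136, 279) and 95 (24, 71) under these, and to 61 (14, 47) with limma and 60 (16, 44) with limma on median-centred values. The summed and 3 of 4 settings ask less of the replicates, and limma uses their spread. Without replicate 1, 2, 3 or 4 the calls numbered 325 to 337 (222 to 234 higher, 99 to 109 lower) for non-canonical use and 280 to 293 (85 to 90 higher, 190 to 208 lower) for efficiency. EdgeR called 257 and 177 pairs, of which 203 and 133 were shared, and limma called 200 for non-canonical use, of which 120 were shared. Count minimums of 1, 50 and 100 gave 266, 260 and 248 calls of non-canonical use and 231, 197 and 185 of efficiency. As differences in percent, replicates correlated with a mean r of 0.812 for non-canonical use and 0.494 for efficiency, the cause was not tested. The kidney share of 75% was 66.7% with 1 pair per gene and 50% without genes in another list, with fewer pairs tested and neither past the threshold. EdgeR kept 27 of 28 named calls of non-canonical use and 29 of 32 of efficiency, and limma 24 and 23, ending those of G22T of PFKFB2 and YOD1, BACE1, LAMP2 and TSC2 G26A in non-canonical use and, among others, of ULK3, PPP1CA, LMNA, MYH7, RB1, BTK A23C, COL4A5 A18G and SPG11 in efficiency; all were kept with summed counts and without any 1 replicate. Efficiency rests on a median of 25 to 33 unspliced reads per oligonucleotide. The alternatives for branch site position and source database were not run, because those results are not analysed here.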

Other observations

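All values in this part were chosen after the data were seen. The base at chromosome 17, 47151947 (CDC27, a gene of the anaphase-promoting complex) was tested in 2 overlapping windows. As A29G it lowered non-canonical use from 11.9% ± 1.33 to 4.42% ± 1.60, and as A11G from 10.7% ± 1.16 to 4.15% ± 0.561 (n = 4), both called. The exon starts of the 2 windows differ, so reads counted as canonical are not at the same site. A base of DGKA, a lipid kinase gene, tested as C10T and as C72T was called in neither. Among other mutants that shared the wildtype of a called pair, 4 of 30 were also called for a rise in non-canonical use, 0 of 13 for a fall in it, 6 of 29 for a fall in efficiency and 2 of 12 for a rise in efficiency.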
